A study of Canis lupus familiaris with 51 samples.

How the data were processed

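RNA was measured by sequencing in 51 dog tumours labelled as hemangiosarcoma, a malignant tumour of cells related to blood vessel lining. The histogenic origin of 1 of them is labelled as undetermined. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a TruSeq kit. The authors deposited 1 table of FPKM values (fragment counts scaled by transcript length and by the mapped total of the library) with 16382 genes and 1 column per tumour. Per the submitters' processing notes, FastQC 0.11.2, TopHat 1.4.1 and Cuffdiff were used with the dog genome build CanFam3.1. The version of Cuffdiff, the gene annotation, strand settings and any filter are not given in the sources used here. Whether the authors scaled the deposited FPKM between libraries is likewise not given in the sources used here. The upper quartile of FPKM lay between 22.45 and 26.09 in the 51 libraries, while the sum of FPKM ran from 405227.2 to 1057712.

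The genes carry Ensembl identifiers, the files do not pair them with symbols, and 0 of the 16382 matched the symbol table of assembly UU_Cfam_GSD_1.0 used here. The gene lists fixed before the data were examined (blood vessel, immune, muscle, liver and other cell type lists) could not be scored for this reason. The rule for named genes required a symbol and so named none. 4 identifiers are printed. They were chosen after their values were seen, as the largest fold in the heart comparison, the single gene called between breeds and the genes with the smallest adjusted p in the sex by organ comparison.

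Fragment counts were not part of the data. In low genes the FPKM values are whole multiples of the value of 1 fragment, so relative depth could be solved from the steps of 1891 low genes. In a median pair of libraries 22.1% of the low genes shared the main step, within a window of 0.04 on the log2 scale, and 100% of pairs lay within 0.05 of the solved depths. On simulated data the largest error was 0.0 on the log2 scale. Only relative depth is known, so no counting interval or detection floor was computed. It follows the scaling in the deposited FPKM, and equals relative sequencing depth only if no other scaling between libraries was applied.

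Groups were taken from the tissue labels: spleen (32 tumours), heart (11), liver (3), and 5 labels with a single tumour each, which entered no test between groups. Replicate numbers follow the order of the samples and pair nothing. Labels give breed, sex with neuter status, and age, and do not state that every sample came from a separate dog, so p-values measure the spread between these samples. The most similar pair of libraries had a correlation of 0.963 and the median pair 0.886, so none was treated as a duplicate.

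Values were analysed as log2(FPKM + 1), and fold changes are on that scale, which understates the change of low genes. Genes with at least 1 FPKM in at least 3 fitted tumours were tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean trend, Benjamini-Hochberg adjustment, adjusted p under 0.05, two-sided). The organ comparisons shared 1 fit over 46 tumours without covariates. Sex, breed class and age were each fitted with organ as a covariate, and neuter status with organ and sex. Sample titles have the prefixes CHAD or DHSA, whose meaning is not given in the sources used here, and these were compared within spleen as a possible batch. Interaction terms over the 43 spleen and heart tumours tested whether a breed or sex effect differed between organs. These comparisons and the other settings tried for them (pseudocount 0.1, other filters, median-ratio rescaling, quantile normalization, robust fitting, array weights, covariates, subsets) were fixed before the data were examined.

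In simulations with 100 genes changed by 1 and 100 by 2 on the log2 scale, the heart comparison recovered 85% and 96% of them, the liver against spleen comparison 47% and 83%, and the comparison of titles 53% and 89%. The sex, neuter status and breed simulations recovered 87%, 86% and 88% of changes of 1. Between 0 and 7 unchanged genes were also called in these simulations, except for 86 in that for sex. All changed genes were planted together, which eases the adjusted threshold, so recovery would be lower where few genes differ.

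Other steps were chosen after the data were seen. Principal components were computed over the 46 tumours and the first 5 were tested against 7 factors (100000 permutations, within organ except for organ itself, 35 tests adjusted together). Gene modules were found in the 32 spleen tumours from the 3000 most variable genes by average linkage at a correlation of 0.5, with at least 25 genes each. A module's level is the mean log2(FPKM + 1) of its genes. Module levels were tested with permutation tests, exact for liver, 108 tests adjusted together. Sparse genes (median under 1 FPKM over 51 tumours, at least 20 FPKM in 1) were clustered at a correlation of 0.6 into blocks of at least 10 genes. A gene was counted as private to a tumour at 5 FPKM or more and at least 4 times its level in every other tumour. In simulated data, 60 of 60 planted genes were found in each module, and 5.5% of null tests had a p under 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.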

Results

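Transcript levels were measured in 51 canine tumours labelled as hemangiosarcoma, from spleen (n = 32), heart (n = 11), liver (n = 3) and 5 further sites or categories with 1 tumour each. For 1 of the single tumours the tissue label gives the histogenic origin, that is, the tissue the tumour arose from, as undetermined. Spleen and heart are common primary sites of this tumour in dogs. The spleen tumours came from 16 females and 16 males, the heart tumours from 3 females and 8 males, and the liver tumours from 3 females. Golden Retrievers gave 20 of the spleen, 6 of the heart and 1 of the liver tumours. Age at diagnosis was 10.2 ± 2.15 years in spleen, 9.17 ± 1.91 years in heart and 10.17 ± 0.67 years in liver (mean ± SD). The dog with the tumour of undetermined histogenic origin was 0.7 years old. Relative depth, as solved from the FPKM steps, ran from 0.526 in spleen 7 to 2.133 in spleen 13. It averaged 1.06 ± 0.3 in spleen, 1.12 ± 0.24 in heart and 1.23 ± 0.2 in liver (SD). At least 1 FPKM was reached by 11201.41 ± 226.55 genes in spleen, 11214.27 ± 282.77 in heart and 11100.67 ± 203.53 in liver (SD), so the organs differed by less than the spread within them.

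The main axes of variation ran across the organs. The first principal component held 23.1% of the variance over the 46 spleen, heart and liver tumours, and organ accounted for 12.7% of it (permutation p = 0.051, adjusted p = 0.59 over 35 tests). Its scores were 9.4 ± 41.1 in spleen, -21.1 ± 32.8 in heart and -22.8 ± 20.4 in liver (SD). The smallest raw p values were 0.042 for relative depth on the first component and 0.044 for sex on the fourth, each with an adjusted p of 0.59. None of the 35 tests passed after adjustment.

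Heart tumours were compared with spleen tumours to ask which transcripts differ by site of origin. 20 of 12887 genes were higher in heart and 0 were lower (limma, adjusted p under 0.05), 15 of them by at least 2-fold, with log2 fold changes from 0.68 to 3.33. At an unadjusted p under 0.05 there were 1358 genes, 757 higher and 601 lower in heart. The gene with the largest fold, ENSCAFG00000016539, averaged 188 ± 317 FPKM in heart (SD, n = 11) and 0.158 ± 0.187 in spleen (SD, n = 32), a log2 fold change of 3.33 ± 0.69 (SE, limma adjusted p = 0.0249). Its level was 221.6, 493, 368.4 and 981.8 FPKM in hearts 1, 7, 8 and 10, and at most 1.01 FPKM in the other 7 heart tumours, with a heart median of 0.543. This gene lost its call in 8 of 55 other settings. For 17 of the 20 genes the highest heart value was in heart 1, 7, 8 or 10, all from males, and for 2 genes the heart median exceeded every spleen value. A highest value in 1 of these hearts does not mean that all of them were high. A gene among the 17 had 148.4 FPKM in heart 10 but 3.7 and 1.6 in hearts 7 and 8, against 141.1 and 108.4 in hearts 4 and 9.

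The mean log2 level of the 20 genes was 3.34, 3.78, 3.77 and 4.63 in hearts 1, 7, 8 and 10. In the other hearts it ran from 1.3 to 2.38 and in the spleen tumours from 0.6 to 2.11. The 3 liver tumours had 1.74, 1.29 and 1.17. The cutaneous tumour had 1.36, the metastatic tumour 1.2, the abdominal masses 1.5 and 1.32, and the tumour of undetermined histogenic origin 0.67.

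**Figure D1:**
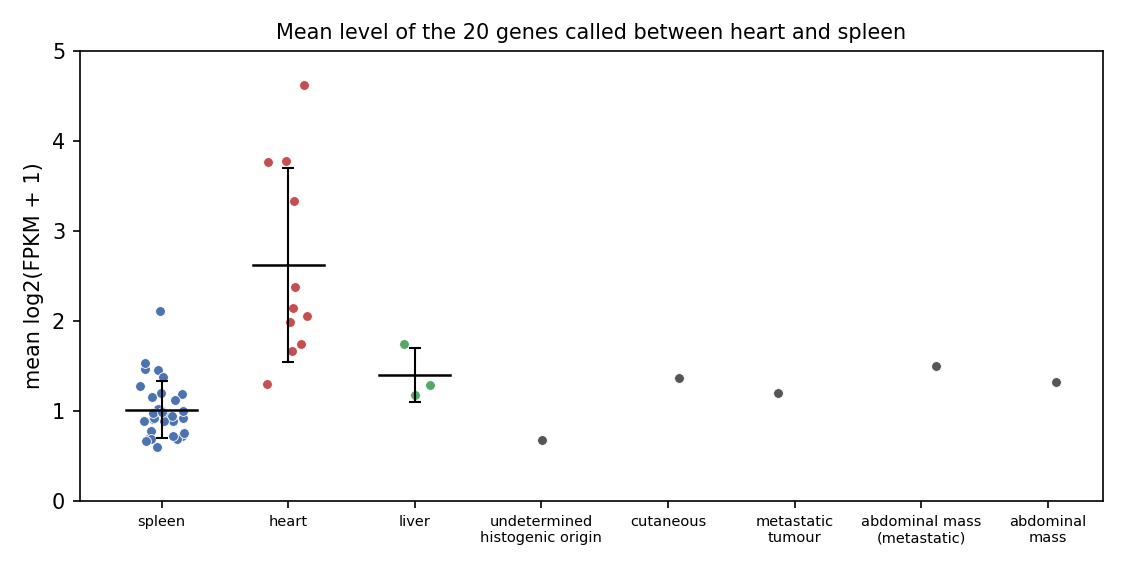
Mean log2(FPKM + 1) of the 20 genes called between heart and spleen, 1 point per tumour, with horizontal lines for group means and bars for 1 SD where a group has more than 1 tumour. Hearts 1, 7, 8 and 10 lie between 3.34 and 4.63, above the highest spleen tumour at 2.11. The genes were selected for this difference.

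The size of the heart list depended on single libraries and on the model. Without heart 1, 7, 8 or 10 the count was 5, 5, 6 and 4 genes, and without heart 2, 3, 4, 5 or 11 it was 31, 32, 35, 48 and 40. Leaving out 1 spleen tumour gave 11 genes for spleen 4, 5, 7, 18, 19, 21, 28, 29 or 32, 12 for spleen 11, 24 or 25, and 13 for spleen 1 or 26. With sex, neuter status, breed class and age as covariates 6 genes were called, without the CHAD titles 5, in Golden Retrievers 2, and among genes with a mean of at least 5 FPKM 0 (951 at an unadjusted p under 0.05). Heart 1 is the only heart tumour with a CHAD title, so leaving out these titles also left out heart 1. Array weights, which give less weight to libraries far from the fit, called 499 genes, 269 higher and 230 lower in heart.

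Liver tumours were compared with spleen and with heart tumours in the same fit. limma called 0 of 12887 genes between liver and spleen, with 778 at an unadjusted p under 0.05 (472 higher, 306 lower in liver) and a smallest adjusted p of 0.078. Between liver and heart it called 0 genes, with 693 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0504. Leaving out liver 1, 2 or 3 gave 10, 17 and 1 genes against spleen and 8, 5 and 0 against heart. With 3 liver tumours, a simulated 2-fold change was recovered in 47% of genes, with many genes changed at once.

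Gene modules, groups of genes whose levels rose and fell together across the 32 spleen tumours, described the variation within the organ. There were 18 modules with 2075 genes, and these groups carry no names because the identifiers are not paired with symbols. The largest held 512 genes with a mean pairwise correlation of 0.631 in spleen, and its level ran from 1.842 to 5.112 among spleen tumours. The same genes had a mean correlation of 0.598 over the 11 heart tumours, against a highest value of 0.036 in 1000 random lists matched on expression in heart. The second, with 310 genes, had 0.592 in spleen and 0.401 in heart, against a highest random value of 0.026. The third, with 222 genes, rested on few tumours and was highest in spleen 27 and spleen 17, at levels of 6.98 and 6.347. Its correlation in spleen was 0.738 with all tumours, 0.116 without the 3 highest, and 0.195 in heart. The 4th, with 169 genes, had 0.704 in spleen and 0.334 in heart. Random lists were drawn from all tested genes, not from the most variable ones. The 222-gene module was built apart from the block of 222 sparse genes described below, and their overlap is not given here.

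Levels of these modules did not separate the organs after adjustment. The 512-gene module was at 3.33 ± 0.98 in spleen, 2.75 ± 0.86 in heart and 2.53 ± 0.45 in liver (SD), with a permutation p of 0.092 for heart against spleen (adjusted p = 0.76). The 310-gene module was at 4.23 ± 0.96 in spleen, 4.79 ± 0.51 in heart and 5.09 ± 0.41 in liver (SD), with p = 0.074 for heart by permutation (adjusted p = 0.76). The smallest p for heart was 0.028, for the 169-gene module at 3.1 ± 1.19 in spleen and 2.26 ± 0.5 in heart (permutation, adjusted p = 0.76). None of 108 permutation tests of 18 modules against heart, liver, sex, breed class, age and neuter status passed, and the smallest raw p was 0.014, for a 68-gene module and sex (adjusted p = 0.76). That module rested on few libraries, since its mean correlation in spleen was 0.636 with all tumours and 0.144 without the 3 highest.

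**Figure D2:**
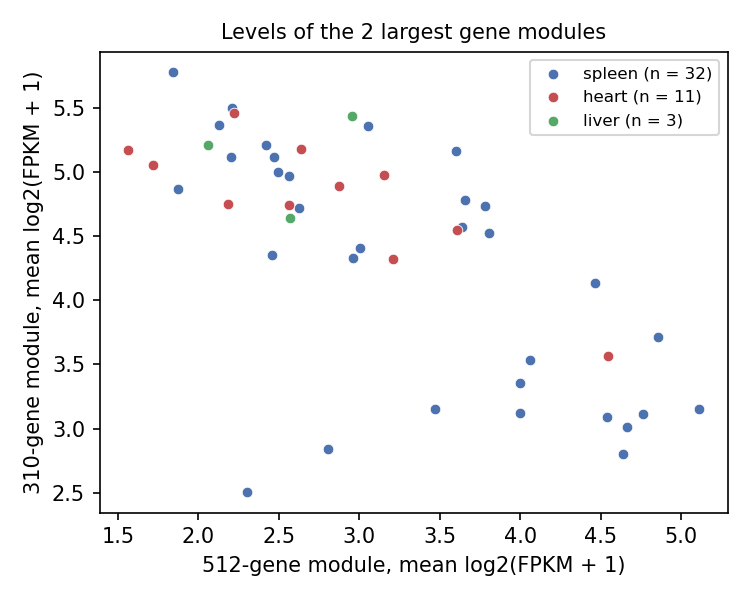
Levels of the 512-gene module (x axis) and the 310-gene module (y axis), each a mean log2(FPKM + 1), 1 point per tumour. Spleen tumours run from 1.842 to 5.112 on the x axis, and r is -0.63 among them.

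Male and female dogs were compared over the 46 tumours (22 female, 24 male) with organ as a covariate. limma called 0 of 12887 genes, with 861 at an unadjusted p under 0.05, of which 286 were higher and 575 lower in males. The simulation recovered 87% of 2-fold changes at this size and also called 86 unchanged genes. Many genes were changed at once in it, so recovery would be lower if only a few genes differed. Genes on the sex chromosomes could not be picked out, because the files pair no gene with a symbol or position, so the sex labels were not checked against expression. Neutered dogs (n = 28) were compared with intact dogs (n = 18), and limma called 0 genes, with 435 at an unadjusted p under 0.05.

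Whether the sex effect differed between heart and spleen was tested with an interaction term over 43 tumours. For 8 of 12844 genes the male minus female difference was more negative in heart than in spleen (limma, adjusted p under 0.05). The interactions ran from -1.63 to -6.97 on the log2 scale, with these genes higher in female than in male hearts. In the other direction 0 genes were called. ENSCAFG00000009613 had an interaction of -6.97 ± 1.01 (SE, limma adjusted p = 0.000255), with 2747.3, 2.9 and 869.8 FPKM in the female hearts 2, 3 and 6, and at most 3.545 FPKM in the 8 male hearts. Its mean was 0.619 ± 1.61 FPKM in female and 0.253 ± 0.929 FPKM in male spleen tumours (SD, n = 16 each). ENSCAFG00000004810 had an interaction of -5.04 ± 0.759 (SE, limma adjusted p = 0.000307). Its female heart mean was 122 ± 105 FPKM (SD, n = 3), and its highest male heart value was 0.522 FPKM. For 8 of the 8 genes the highest value among the 43 tumours was in heart 2 or heart 6. Without heart 2 the count was 0 genes, without heart 6 it was 2 with 1 shared, and without heart 3 it was 34. The median interaction of the 8 genes was -3.41 without heart 2 and -3.13 without heart 6, against -4.26 with all tumours. Without both hearts 1 female heart was left, and the median was -1.1 over the 6 genes still tested. Hearts 2 and 6 came from intact females and heart 3 from a spayed female.

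**Figure D3:**
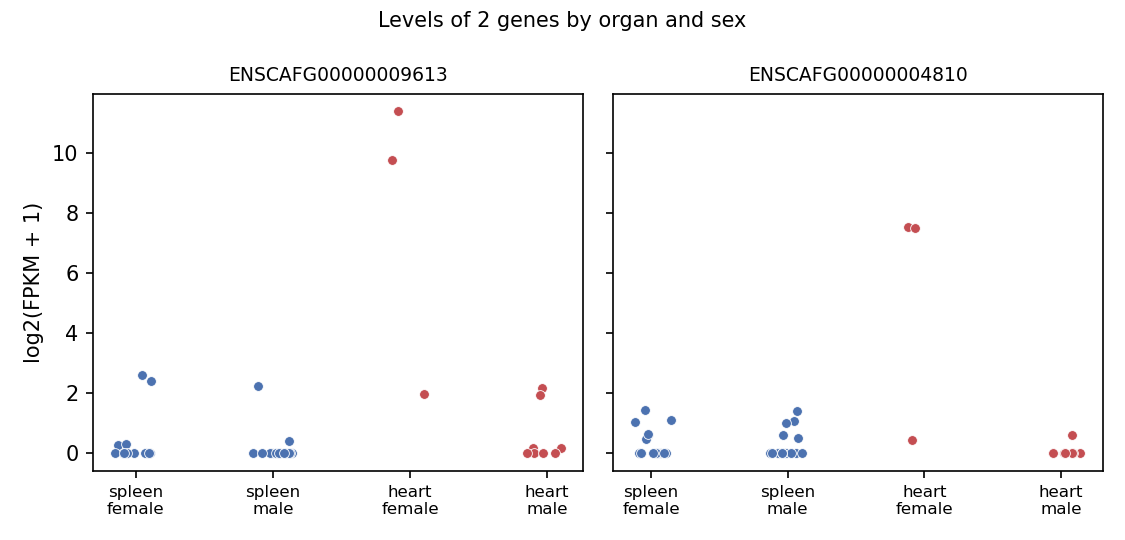
Levels of the 2 named genes on a log2(FPKM + 1) axis, 1 point per tumour, by organ and sex. In each panel 2 of the 3 female heart tumours lie apart from all other tumours, and ENSCAFG00000009613 reached 2747.3 FPKM in heart 2.

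Golden Retrievers (n = 27) were compared with dogs of other breeds (n = 19), since this breed was the most frequent in the series. 1 of 12887 genes was called, with 302 at an unadjusted p under 0.05. ENSCAFG00000008634 was at 8.3 ± 3.44 FPKM in Golden Retrievers and 3.54 ± 1.84 FPKM in other breeds (SD), a log2 fold change of 1.05 ± 0.182 (SE, limma adjusted p = 0.0097). Without heart 5, heart 11 or spleen 30 the count was 3, 3 and 2. Without the CHAD titles and in spleen tumours alone it was 0 (332 and 260 at an unadjusted p under 0.05). The log2 fold change of the gene was then 1.03 (limma adjusted p = 0.139) and 0.81 (limma adjusted p = 1.0), against 1.05 with all 46 tumours. The breed effect did not differ detectably between heart and spleen, where limma called 0 of 12844 genes, with 551 at an unadjusted p under 0.05.

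Age at diagnosis was tested as a slope per year. limma called 0 of 12887 genes, with 883 at an unadjusted p under 0.05 (454 higher, 429 lower with age) and a smallest adjusted p of 0.41. The CHAD titles (n = 5) were compared with the DHSA titles (n = 27) within spleen as a possible batch. limma called 0 of 12645 genes, with 512 at an unadjusted p under 0.05.

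Some gene groups were near 0 in most tumours and high in others. Among 605 such sparse genes, there were 7 blocks of at least 10 genes. A block of 152 genes had a median of 43.65 FPKM in the tumour of undetermined histogenic origin, where 152 of its genes reached 10 FPKM. A block of 40 genes had a median of 62.62 FPKM in spleen 20. A block of 14 genes had medians of 11.25, 33.73, 27.61 and 47.01 FPKM in hearts 1, 7, 8 and 10, and 4 of its genes, ENSCAFG00000016539 among them, were also called between heart and spleen. Another of 11 genes had 39.71 and 55.95 FPKM in hearts 2 and 6, and 4 of its genes, ENSCAFG00000009613 among them, were also called in the sex by organ test. A block of 43 genes was spread over more tumours, with medians of 29.66, 25.59, 22.87, 16.01, 15.36, 10.09 and 10.05 FPKM in spleens 7, 18, 29, 30, 19, 25 and 11, and of 7.66 FPKM in heart 5. A block of 222 genes had medians of 104 FPKM in the metastatic tumour, 33 in spleen 27 and 19.8 in spleen 17. It took 11.4%, 4.83% and 3.3% of the summed FPKM of these tumours. In spleen 27 a single gene stood at 92324.2 FPKM, 8.73% of the sum, and the 10 highest genes took 29.96%.

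**Figure D4:**
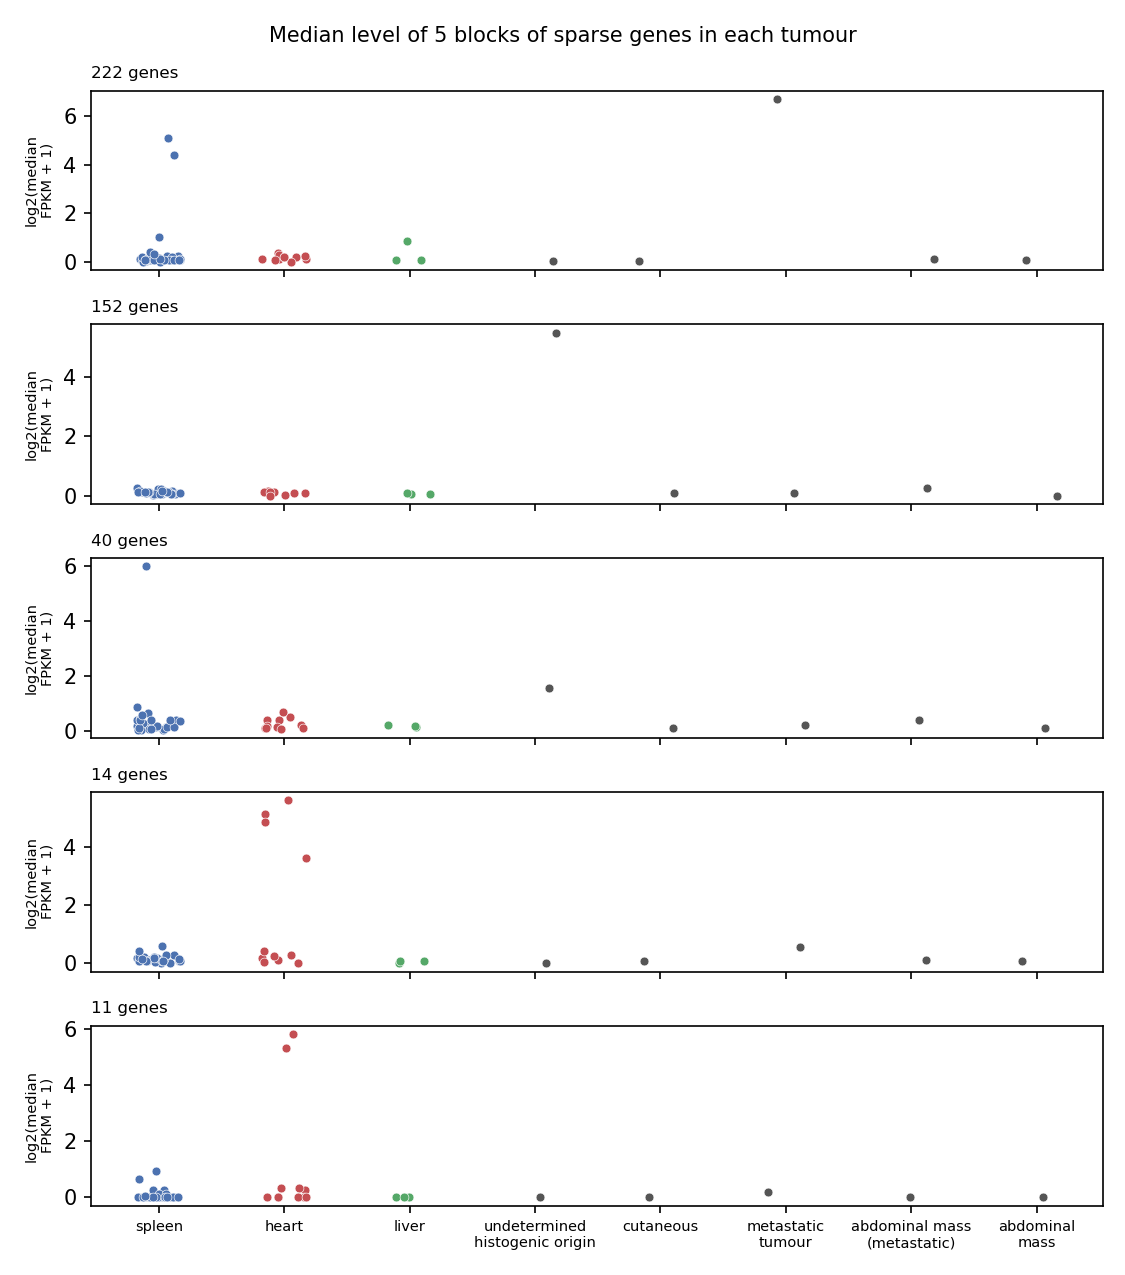
Median level of 5 blocks of sparse genes in each tumour, on a log2(median FPKM + 1) axis, 1 point per tumour and 1 panel per block. The 222-gene block is high in the metastatic tumour and 2 spleen tumours, and the 14-gene block in 4 heart tumours.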

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

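The tests in this part were chosen after the results they bear on were seen, apart from the gene counts and the interaction term themselves and the comparison of ratio spreads in the 222-gene block.

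The sex effect differed between heart and spleen for 8 genes, which stood out because the interaction term tested the difference itself. Chance could not be excluded, since 6 of 100 splits of the samples, the real one included, gave at least 8 genes and the highest other split gave 36. What set that split apart was not examined. Hearts 2 and 6 carried most of the pattern: without both, 0 genes were called and the median interaction was 25.8% of its full value over the 6 of the 8 genes still tested, -1.1 against -4.26, and heart 3 lay at or below the highest male heart for 5 of the 8 genes. Whether a part remains in other female hearts cannot be told apart from the spread with 1 such tumour left, and a biological difference between the sexes was not tested apart from these libraries. Hearts 2 and 6 are labelled as from intact females and heart 3 as from a spayed female. Neuter status among female hearts therefore cannot be told apart from a trait of these libraries.

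Among the tumours outside the comparisons, the tumour of undetermined histogenic origin had 314 private genes and the metastatic tumour had 173, against at most 91 in the 46 spleen, heart and liver tumours. Medians were 1 in spleen, 2 in heart and 4 in liver. The cutaneous tumour had 2, the metastatic abdominal mass 7 and the other abdominal mass 1. The labels give 1 tumour for each of these categories, and no test was run on them. The tumour of undetermined histogenic origin came from a dog of 0.7 years, and the 46 tumours from dogs of 3 to 13.6 years. Age and tumour category cannot be told apart for the private genes of that tumour.

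The metastatic tumour shared a block of 222 sparse genes with spleen 27 and spleen 17, with medians of 104, 33 and 19.8 FPKM and correlations of log2 level across these genes of 0.67 to 0.85 (genes are not independent replicates). Spill of RNA from the metastatic tumour into the spleen libraries was argued against as the whole source of the block. Of the 222 genes, 13.1% were higher in spleen 27 or spleen 17, 18 of them more than 2-fold. Spill was not excluded for the other genes, on which this test does not bear. Whether all 3 tumours held the same kind of tissue or cell at different amounts could not be decided. The spread of ratios in the block was compared with that of other genes matched on level. Such genes need not vary between tumours as genes of a given tissue do, so a wider spread does not exclude a shared tissue. The SD of log2 ratios over the block was up to 1.88 times that of other genes of matched level, namely 1.96 against 1.04 between the metastatic tumour and spleen 27, and 1.44 against 1.04 and 1.34 against 0.96 in the other pairs. The same tissue at different amounts, or related but differing tissues or tumour states, may account for the block. No further explanation was tested, and no cell type could be scored without gene symbols.

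For the 20 genes higher in heart, 1 of 100 splits, the real one, reached 20 and the highest other gave 17. This is weak evidence against chance for that count and does not exclude it. Other comparisons were put through the same check, and its bound was set after the values were seen. The count was 5, 5, 6 and 4 without heart 1, 7, 8 or 10. The 1358 genes at an unadjusted p under 0.05 were matched by 8 of 100 splits, the highest other with 2293, so chance was not excluded for that number. A difference between organs in relative depth, as solved here, was argued against, because 17 of the 20 genes were still called with it as a covariate. The mean log2 level of the 20 genes was 3.34 to 4.63 in hearts 1, 7, 8 and 10. It was 1.3 to 2.38 in the other hearts and 0.6 to 2.11 in the spleen tumours. For these genes as a set, this argues against an even difference over all hearts. The level is a mean over the 20 genes, and single genes among them were also high in other hearts. Another kind of tissue or cell in hearts 1, 7, 8 and 10 could not be told apart from a difference between the tumours themselves. The mean correlation between the 20 genes over the heart tumours was 0.36 against 0.15 over the spleen tumours, the genes were selected for being high in heart, and the organ of origin stays open as a biological explanation.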

How the results depend on the processing

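Alternatives added after seeing the data were relative depth as a covariate, leaving out spleen 17 and spleen 27, leaving out single libraries for the heart, breed and interaction results, and those for modules. Leaving out heart 2 and heart 6 together was also added. Of the alternatives for gene counts other than leaving out 1 library, 84 stayed within 1.5 times the reported count and 28 did not. A reported 0 that stayed 0 is among the 84. These totals therefore say little about the heart, breed and sex interaction counts, whose changes are listed below. The cause of the changes was not tested. Some of these settings also fitted fewer genes or samples. Heart against spleen (20 genes) gave 11 with pseudocount 0.1, 0 at a mean of at least 5 FPKM, 499 with array weights, 5 without CHAD titles, 6 with covariates and 2 in Golden Retrievers, and 4 to 48 without 1 library. Liver against spleen (0) gave 3 without a filter, 11 with array weights, 33 in Golden Retrievers, 1 with depth as a covariate, and 1 to 17 without 1 liver tumour. Liver against heart (0) gave 4 without a filter, 3 at a mean of at least 5 FPKM, 2 after quantile normalization, 3 with robust fitting, 7 with array weights, 50 in Golden Retrievers, 2 without spleen 17 and 27, 3 with depth, and 0 to 8 without 1 liver tumour. The Golden Retriever fits hold 1 liver tumour, assumed to vary like the others. The fits without CHAD titles also lack heart 1. Male against female (0) gave 3 with array weights. Golden Retrievers against other breeds (1) gave 4 with array weights, 0 without CHAD titles, 0 in spleen, and 1 to 3 without 1 library. The breed interaction (0) gave 5 with array weights and 0 without any 1 heart. The sex interaction (8) gave 5 with pseudocount 0.1, 26 without a filter, 74 with array weights, 13 without spleen 17 and 27, 0 without hearts 2 and 6, and 0 to 34 without 1 heart. The titles comparison stayed at 0 without any 1 CHAD tumour. For the 4 named genes and the correlation of the 512-gene and 310-gene modules no direction reversed in the settings run, and the number of modules called between heart and spleen stayed at 0. Other module values were not run under alternatives. The named heart gene lost its call in 8 of 55 settings, with log2 folds there of 2.69 to 4.74 against 3.33. The breed gene lost its call in 2 of 58, at 1.03 and 0.81 against 1.05. The named sex interaction genes lost theirs in 2 and 3 of 21, at -5.12 and -1.22 against -6.97, and at -3.86, -3.87 and -0.33 against -5.04. The gene list tests, list score correlations and list score covariates were not run, because no identifier matched a symbol. No paired analysis was possible because replicate numbers follow sample order. Absolute depth is unknown, so the limit it sets on low genes was not computed.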

Other observations

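The module correlations in this part, and the counts of splits, were chosen after the data were seen. The 512-gene and 310-gene modules moved in opposite directions across tumours. In the 32 spleen tumours r was -0.63 (permutation p = 0.00016, adjusted p = 0.00096 over 12 tests) and rho -0.64 (p = 0.00017), and r was -0.61 without the 2 tumours farthest from the median. In the 11 heart tumours r was -0.82 (permutation p = 0.0025, adjusted p = 0.0095) and rho -0.68 (p = 0.025), but without the 2 farthest tumours r was -0.58 with a permutation p of 0.1, so the test in heart rested on those. The 512-gene and 169-gene modules rose together in spleen, with r = 0.75 (p = 1e-05, the smallest the permutations can give) and rho 0.74 (p = 1e-05), and r = 0.82 without the 2 farthest. In heart their r was 0.79 (permutation p = 0.0032) and rho 0.7 (p = 0.021), and r fell to 0.36 without the 2 farthest, so it rested on those tumours. The spleen correlation of the first pair was between -0.59 and -0.67 under other pseudocounts, scalings and subsets. The 310-gene and 169-gene modules had r = -0.45 in spleen and -0.81 in heart (permutation, adjusted p = 0.027 and 0.032). Their rho was -0.31 in spleen and -0.53 in heart (permutation p = 0.087 and 0.1). For the pairs with the 142-gene module r did not pass in either organ, with a smallest adjusted p of 0.25 by permutation.

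For the other gene counts, splits of the same samples gave these results. For breed, 2 of 100 splits, the real one included, gave at least 1 gene, and the other of these gave 281. What set that split apart was not examined. For liver against spleen, liver against heart, sex, neuter status, age, titles and the breed interaction the count was 0, so 100 of 100 splits gave as many. The highest other splits gave 148, 35, 3, 2, 189, 383 and 39 genes.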
